A study of Marchantia polymorpha with 4 samples.

How the data were processed

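RNA of the mutant Mpjaz-1 and of the wild type Tak-1 was hybridised together on 4 Agilent 2-colour arrays. Per the labels' protocols, plants were grown for 3 weeks on Gamborg B5 medium at 0.5 strength with 1% agar, and 200 ng of total RNA per sample was amplified and labelled with Cy3 or Cy5. Extraction used one of 2 kits, and the labels do not say which kit served which replicate. Per the labels, each replicate is an independent biological one of 6 to 8 plants.

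The deposited scanner files give spot intensity, as the mean pixel signal and the median local background in Cy3 and Cy5, per the file headers from Agilent Feature Extraction 10.7.3.1. Processed signals in the same deposited files are an intensity after background subtraction, detrending and dye normalization by linear and lowess fits, per the file headers. The log10 ratio of processed Cy5 over Cy3 stands in the same files, per the file headers. Flags for spots above background, saturated or outlying are also deposited there. For the whole series the authors deposited a log2 value per spot and array in a table. Its scale, centring and direction are not stated and were found by comparison with the scanner signals. Each column has a mean of 0, and the column medians are 0.07, 0.06, −0.07 and 0.04 for replicates 1 to 4. Against own log2(Cy3/Cy5) values the slopes were 0.949, 1.01, −0.945 and 1.03, so the scale is log2 and replicate 3 has its sign turned. The normalization behind the table is not given in the sources used here.

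Signals were read in R 4.3.3 and analysed with limma 3.58.1 and data.table (version 1.17.8). Background was corrected with normexp and an offset of 50, fitted on all spots, control spots were given weight 0, outlier spots were left out, and global loess with a span of 0.3 was applied within each array. Spots of a probe were averaged, giving 40422 probes from 60103 spots. A probe was kept when it was well above background in Cy3, Cy5 or both on at least 3 arrays, which left 21164 probes. Probes of a gene were averaged, leaving 11000 of 19217 genes, of which 8971 carry annotation text. Of the kept genes 9424 have over 1 probe, and every probe of the 1063 called genes with over 1 probe lay on the same side of 0. Calls were made on the mean of those probes, which favours such agreement. Kept genes that share probe sequence with another gene number 84, 17 of them called. Gene identifiers and the best Arabidopsis match are those of the array annotation. The reference table of this species, of assembly MpTak2_v7.1, holds none of these identifiers, 0 matched, and no coordinates are given.

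The test was limma's lmFit of 1 ratio per array on an intercept with eBayes, two-sided, with Benjamini-Hochberg adjustment over the genes kept and a threshold of 0.05. The design fixed before the data were examined took all 4 arrays with the signs of the labels. Since replicate 3 ran opposite, the same fit with replicate 3 turned was added after the data were seen, as was one with a dye term. Under the labels there is no dye swap, so that a gene-specific dye effect cannot be told apart from genotype. Gene lists were 32 text patterns over the annotation fixed before the data were examined, of which 31 had the 5 measured genes needed for a test. They were compared with other genes by limma's camera with a preset correlation of 0.01, and with an estimated correlation and fry beside it. With an estimated correlation, camera takes its degrees of freedom from the few arrays, so it had little power after adjustment. A call lost there does not argue against a list. Named genes were chosen by a rule fixed beforehand: MpJAZ and the called members of the jasmonate lists, the 12 largest rises and 12 largest falls among called genes with annotation and the same sign on 4 arrays, and in each list the 2 to 4 members with the smallest p. A gene not well above background in a genotype on every array was to be given as a bound, from per-channel values after loess and Aquantile normalization, which are open to dye bias. No gene was saturated.

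The fit was tested on simulated ratios of 10997 genes with the spread of the arrays with replicate 3 turned, 40 genes at each of 5 changes. Of genes changed 2-fold 22.5% were recovered, of those changed 4-fold 72.5% and of those changed 16-fold 100%. Among 10797 unchanged genes 8 were called, and 0 were called when no gene was changed. Simulated values were drawn independently across genes and arrays. These rates therefore do not cover effects shared by the arrays of a slide or by groups of genes. Alternatives covered the background correction, the authors' deposited table, normalization within and between arrays, the filter on dim probes, the summary of probes, slide as a block and each slide alone, each array left out, the variance model and separate channels. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

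Signal in Cy3 was close to its background. Negative controls in Cy3 had an average net signal, per the scanner software, of 2707, 2689, 1221 and 1885 on replicates 1 to 4. The median of the mean pixel signal over all spots, a different statistic, was 3052, 2993, 1438 and 2172 in Cy3. Cy5 negative controls had an average net signal of 49.1, 49.0, 37.1 and 37.4. From 28.1% to 44.4% of spots were well above background in Cy3 and from 46.7% to 55.6% in Cy5. The scanner software marked the grid as good on replicate 3 and as not good on replicates 1, 2 and 4.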

Results

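Transcript levels were compared between the Marchantia polymorpha mutant Mpjaz-1 and the male wild-type accession Tak-1 on 4 Agilent 2-colour arrays, each holding RNA of both genotypes. Marchantia polymorpha is a liverwort whose haploid thallus grows from apical notches. The question named by the series title is what the only JAZ repressor of this plant does in the jasmonate pathway. JAZ proteins hold transcription factors of the MYC type inactive until a jasmonate signal marks them for degradation. Each of the 4 replicates was labelled an independent biological replicate of 6 to 8 plants, grown for 3 weeks on agar, from which apical fragments without gemma cups were taken. After the filter on dim probes, 11000 of 19217 genes on the array were compared, and the number of arrays limits the precision of every value. Genes were named by the Arabidopsis gene that the array annotation gives as the best match, and "like" after a symbol stands for such a match.

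By the labels, the Mpjaz-1 RNA carried Cy3 and the Tak-1 RNA Cy5 on all 4 arrays, yet the Cy3/Cy5 ratios of replicate 3 ran opposite to those of the other 3. Pearson's r of replicate 3 with replicates 1, 2 and 4 across genes was −0.61, −0.61 and −0.70, so the direction of the series is not settled by the labels. In the authors' deposited table, replicate 3 stands with the sign opposite to its own Cy3/Cy5 ratio (r across spots −0.99) and the other 3 stand with the same sign (r of 0.993, 0.991 and 0.991). Values were therefore taken with replicate 3 turned, a reading chosen after the arrays had been compared, and with the signs as labelled beside it. "Mpjaz-1" stands for the RNA so labelled on replicates 1, 2 and 4. The direction is a likely one, resting on the labels of those 3 arrays, the order of the genotypes in the series' design text and the signs in the authors' deposited table. If those 3 arrays were the ones with exchanged dyes, every rise given here would be a fall.

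The targeted gene, MpJAZ (Mapoly0097s0021, best match JAZ1), was higher in Mpjaz-1, not lower. Its log2(Mpjaz-1/Tak-1) was 1.68 ± 0.31 (SD, n = 4), a 3.21-fold difference with a limma adjusted p of 0.00929, and it read 1.61, 1.27, 1.90 and 1.95 on replicates 1 to 4. Both probes of the gene gave a positive mean, 1.78 and 1.59. The kind of lesion in Mpjaz-1 and the place of the probes relative to it are not given in the sources used here, so the level of this transcript does not check which RNA was the mutant's. With the signs as labelled the value was 0.73 ± 1.78 (SD, n = 4) with a limma adjusted p of 0.641, and without replicate 3 it was 1.61 with an adjusted p of 0.0372 by limma. With replicate 3 turned, its call was lost after median centring (1.22, limma adjusted p = 0.209) and with a trended and robust variance (limma adjusted p = 0.0614). With no background correction the value was 0.91 (limma adjusted p = 0.0453). On slide 1, which held replicates 1 and 2, the mean was 1.44, and on slide 2, which held replicates 3 and 4, it was 1.93.

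Of the 23 measured genes of jasmonate synthesis, 7 rose in Mpjaz-1, 1 fell and 15 did not pass the test, and 8 rose and 2 fell when adjusted over the list alone. The largest rises were in genes annotated as lipoxygenases, a family of which some members start the pathway by oxygenating linolenic acid. The list took every gene so annotated, and which of them act in the pathway was not tested. A LOX3-like gene (Mapoly0026s0148) was higher by 6.18 ± 0.62 on the log2 scale (SD, n = 4), or 72.5-fold, and a LOX5-like gene (Mapoly0023s0182) by 5.47 ± 1.05, or 44.3-fold. The remaining lipoxygenases that rose were Mapoly0106s0031, at 2.14, and the LOX3-like Mapoly0191s0014, at 1.85. Allene oxide synthase (AOS-like, Mapoly0185s0014), the next enzyme of the pathway, rose by 1.56 ± 0.85 (limma adjusted p = 0.0481). Acyl-CoA oxidases, which shorten the side chain in the peroxisome, rose by 3.68 ± 0.54 (ACX3-like, Mapoly0007s0119) and 1.04 ± 0.28 (ACX1-like, Mapoly0169s0009). Lipoxygenases did not all move one way: the LOX1-like Mapoly0420s0001 fell by 1.65 ± 0.49. Without replicate 3, 4 members rose and the LOX1-like Mapoly0006s0130 fell (−1.90), while Mapoly0420s0001 did not pass (limma adjusted p = 0.0538). Nor did the AOS-like Mapoly0185s0014, the ACX1-like Mapoly0169s0009 and the LOX3-like Mapoly0191s0014 (limma adjusted p = 0.0797, 0.0564 and 0.0503). The list as fixed was above the other genes by limma's camera (adjusted p = 0.00996, list median 0.13, slide medians 0.03 and 0.40). This was lost with an estimated correlation between genes (adjusted p = 0.873 by limma's camera).

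The list of jasmonate perception and repression had 10 measured members, of which MpJAZ rose, 1 fell and 8 did not pass, with the same counts when adjusted over the list alone. The member that fell, Mapoly0036s0038 (−1.10), matches NDL1, an N-MYC downregulated-like gene with no role in jasmonate perception, which the text pattern of the list caught by its name. The pattern also caught 2 potassium channels, Mapoly0061s0102 and Mapoly0066s0114, by the word rectifying, and neither passed. The list as fixed did not stand apart from other genes by limma's camera (adjusted p = 0.728).

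**Figure D1:**
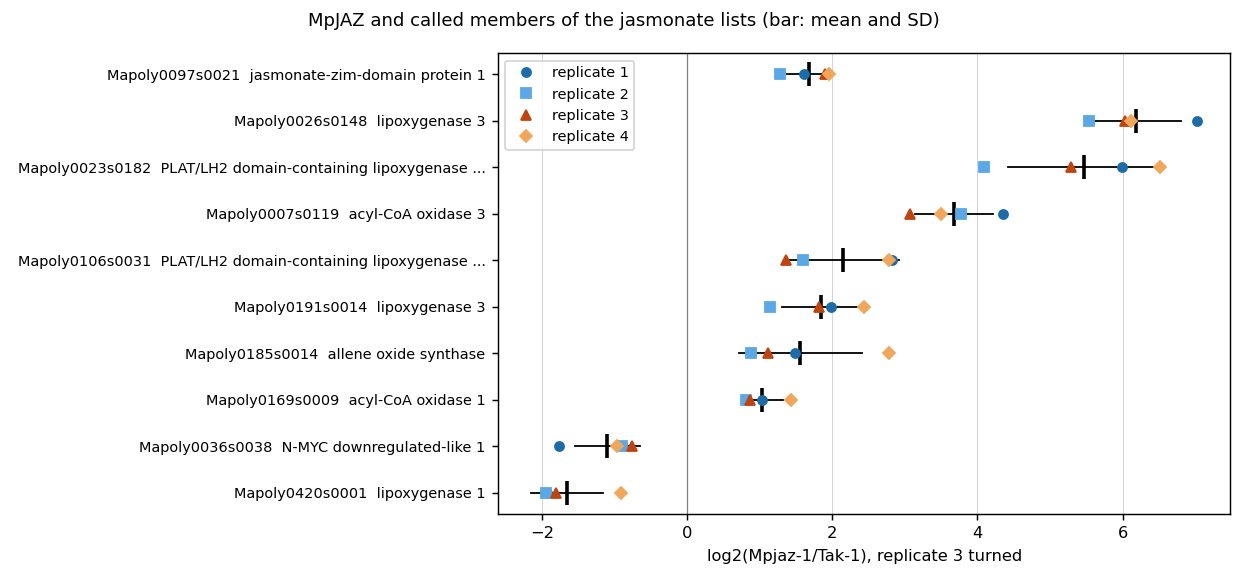
Log2(Mpjaz-1/Tak-1) of MpJAZ (top) and of the called members of the jasmonate lists, with replicate 3 turned. Symbols are the 4 arrays, vertical ticks their means and horizontal bars 1 SD to each side. The LOX3-like gene Mapoly0026s0148 lies between 5.54 and 7.03 on the 4 arrays, and the LOX1-like Mapoly0420s0001 below 0 on each.

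Over all genes kept, 1108 differed between the genotypes with replicate 3 turned, 455 higher and 653 lower in Mpjaz-1 by limma. At least 2-fold differences made up 951 of them, 411 higher and 540 lower. All 1108 had the same sign on the 4 arrays, which the test itself favours. The share of higher genes was 41.1% after loess normalization and 54.2% (109 higher and 92 lower) after median centring alone. With the signs as labelled, limma called 0 genes, 1356 passed an unadjusted p of 0.05 where chance gives 550, and the smallest adjusted p was 0.312 by limma. Without replicate 3, 646 genes passed (186 higher, 460 lower) and 486 of the 1108 were among them with the same sign. Without replicate 1, 209 were higher and 239 lower. The balance turned without replicate 2, with 209 higher and 126 lower, and without replicate 4, with 289 and 192. With slide as a block 935 genes were higher and 1467 lower, on slide 1 alone 893 and 2398, and on slide 2 alone 321 and 156. Called counts fell to 44 higher and 60 lower with a trended and robust variance, and to 123 and 110 with a dye term. The median log2 ratio of all kept genes was −0.14, and it was −0.52 after median centring. Relative to that median MpJAZ stood at 1.83 and 1.74 under the 2 normalizations, and all 113 other named genes kept their sign.

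The list of abscisic acid and desiccation, which is made mostly of late embryogenesis abundant (LEA) proteins, some of which protect drying cells, had 66 measured members. Of these 29 rose, 3 fell and 34 did not pass, and 45 rose and 6 fell when adjusted over the list alone. The LEA families of the list did not all move. In the family annotated as LEA family protein 13 of 19 genes rose, and 7 of 8 annotated as putative LEA proteins did, with 0 falls in each. The 12 LEA hydroxyproline-rich glycoprotein genes had 1 rise, 1 fall and a median of 0.127. The list median was 2.36 (limma's camera adjusted p = 2.91e-14), with 2.22 on slide 1 and 1.73 on slide 2. It was 1.28 with no background correction and 3.55 with Agilent's processed signals. On replicates 1 to 4 the list medians were 2.025, 2.422, 2.585 and 0.824, so that replicate 4 alone stood low. With an estimated correlation the adjusted p was 0.851 by limma's camera. The difference between the slides had an adjusted p of 0.0414 by limma's camera, and of 0.931 with an estimated correlation. The largest rise among annotated genes was in an ECP63-like gene (Mapoly0087s0015), at 6.93 ± 1.36 (SD, n = 4) or 122-fold. ECP63 is a LEA protein of Arabidopsis, and the genes that match it lie outside the list, whose text pattern does not catch the name. The LEA genes Mapoly0119s0007, Mapoly0119s0008, Mapoly0119s0009 and Mapoly0119s0010 rose by 4.42, 1.34, 4.53 and 6.51. A dehydrin (ERD10-like, Mapoly0056s0073) rose by 3.18 ± 0.86. Some of these genes read higher on slide 1: the ECP63-like Mapoly0035s0092 (mean 5.90, limma adjusted p = 0.0476) read 8.30 and 8.99 on replicates 1 and 2, 4.97 on replicate 3 and 1.34 on replicate 4. Without replicate 3 its adjusted p was 0.0915 by limma. Also among the 12 largest rises of annotated genes were the LEA genes Mapoly0053s0070 (6.03) and Mapoly0010s0085 (5.82), the ECP63-like Mapoly0041s0039 (5.98) and Mapoly0033s0100, of a low temperature and salt responsive family outside the list (5.65). They read between 1.76 and 2.48 on replicate 4. The ABI3-like regulator Mapoly0086s0035, a B3 factor of seed maturation in Arabidopsis, rose by 2.15 ± 0.40.

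Other large rises among annotated genes were in a chlorophyllase (CLH1-like, Mapoly0008s0176), which cleaves the phytol chain of chlorophyll, at 6.63 ± 1.60 (99.2-fold), an alpha carbonic anhydrase (Mapoly0060s0019) at 5.78 ± 0.88, a peroxiredoxin (PER1-like, Mapoly0057s0102) at 5.69 ± 2.06 and a PEBP family gene (Mapoly0003s0041) at 5.63 ± 1.14. The largest fall among annotated genes was in the elongation factor gene Mapoly0145s0015, at −4.20 ± 0.62, and its neighbour Mapoly0145s0014, of the same family, was at −3.53 ± 0.33. Glutamine synthetase genes, whose enzyme assimilates ammonium, fell by 3.83 ± 0.85 (Mapoly3414s0001) and 3.41 ± 0.73 (Mapoly0085s0099). A plasma membrane proton pump (AHA11-like, Mapoly0006s0245) fell by 3.49 ± 0.67. Of the called genes, 8 that were higher in Mpjaz-1 were not well above background in Tak-1 and 32 that were lower were not well above background in Mpjaz-1, so that only a lower limit of their change can be given, which is smaller than the fitted ratio in the named case below.

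**Figure D2:**
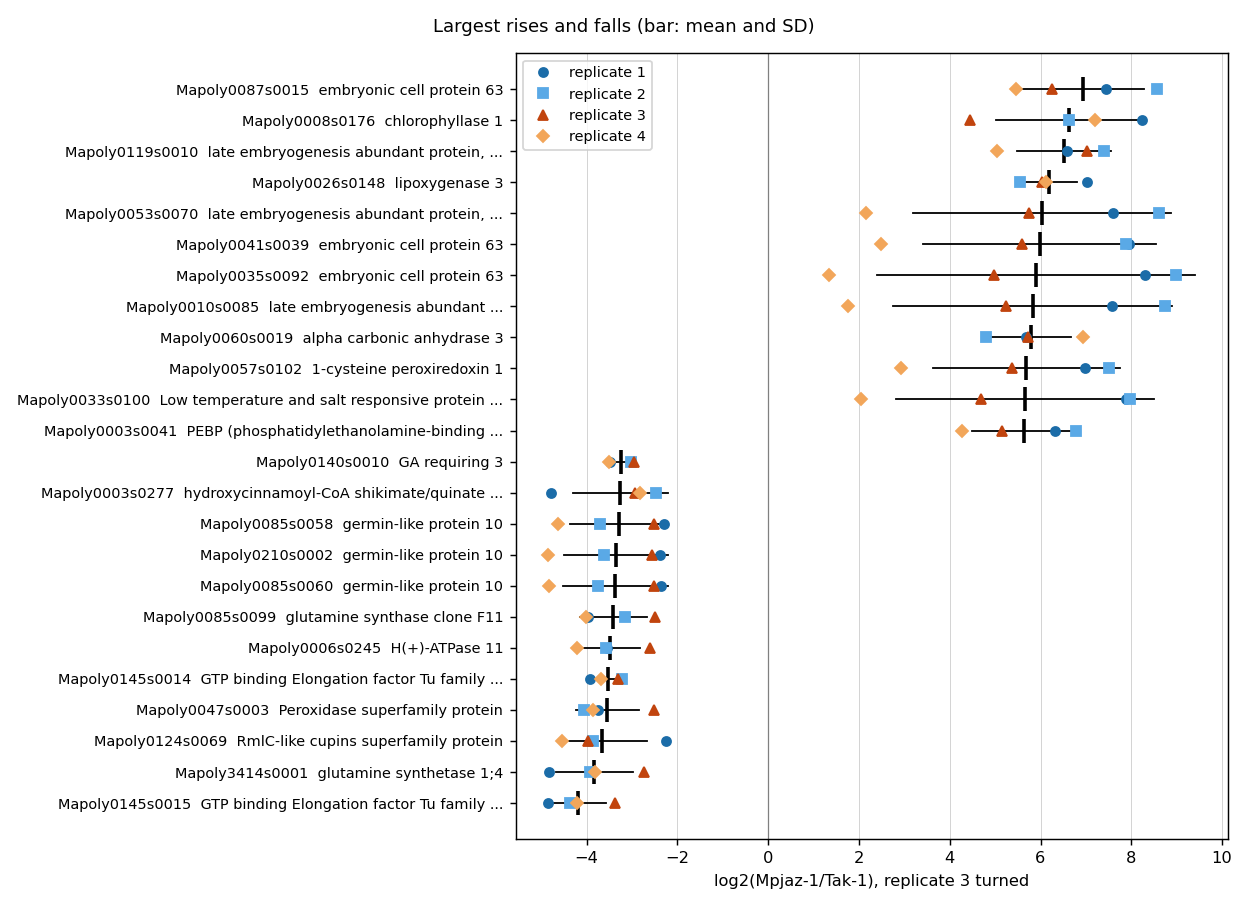
Log2(Mpjaz-1/Tak-1) of the 12 annotated genes with the largest rise and the 12 with the largest fall, with replicate 3 turned. Symbols are the 4 arrays, vertical ticks their means and horizontal bars 1 SD to each side. Several LEA genes read lowest on replicate 4, down to 1.34, while the falls lie between −2.26 and −4.84.

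Of 139 measured class III peroxidases, secreted enzymes that act on the cell wall, 50 fell in Mpjaz-1, 1 rose and 88 did not pass, and 73 fell and 3 rose when adjusted over the list alone. The list median was −0.92 (limma's camera adjusted p = 1.75e-13), with −1.31 on slide 1 and −0.79 on slide 2. With an estimated correlation the adjusted p was 0.851 by limma's camera. The peroxidase Mapoly0047s0003 fell by 3.55 ± 0.69, Mapoly0282s0001 by 3.04 ± 0.16 and Mapoly0009s0175 by 2.99 ± 0.46. Cupins and germins, apoplastic proteins some of which make hydrogen peroxide, had 20 falls, 1 rise and 34 not passing among 55 measured. When adjusted over the list alone 26 fell and 3 rose. Their median was −1.003 (limma's camera adjusted p = 2.33e-06, slide medians −1.29 and −0.76), and with an estimated correlation the adjusted p was 0.851 by limma's camera. The cupin Mapoly0124s0069 fell by 3.65 ± 0.98 and the germin-like Mapoly0028s0004 by 3.22 ± 0.85. The germin-like genes Mapoly0085s0058 and Mapoly0085s0060 fell by 3.29 and 3.37, but they share probe sequence with another gene, so these values are not theirs alone.

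In the cell wall modification list 18 of 79 measured genes fell, 1 rose and 60 did not pass, and 26 fell and 2 rose when adjusted over the list alone. A pectin lyase-like gene (Mapoly0259s0002) fell by 3.00 ± 1.08 and a xyloglucan endotransglucosylase, which cuts and rejoins wall xyloglucan (XTH5-like, Mapoly0008s0185), by 2.47 ± 0.65. The list median was −0.60 (limma's camera adjusted p = 0.00011, slide medians −1.02 and −0.31), and the adjusted p was 0.873 by limma's camera with an estimated correlation. In the mineral uptake list 10 of 60 fell, 2 rose and 48 did not pass, and 17 fell and 4 rose when adjusted over the list alone. An ammonium transporter (AMT1;2-like, Mapoly0081s0029) fell by 1.19 ± 0.31 and a PHT1;1-like phosphate transporter (Mapoly0773s0001) by 1.97 ± 0.81. The list median was −0.57 (limma's camera adjusted p = 0.0142, slide medians −0.80 and −0.24), and with an estimated correlation the adjusted p was 0.873 by limma's camera.

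In the photosynthetic light reactions 5 of 79 measured genes fell, 0 rose and 74 did not pass, with 3 falls when adjusted over the list alone. The LHCB2-like antenna gene Mapoly0199s0017 fell by 2.99 ± 0.61 and a PSBP-like gene of the oxygen-evolving complex (Mapoly0058s0007) by 1.02 ± 0.18. The families of this list, singled out after their results were seen, did not all stand lower. Of 17 chlorophyll A-B binding family genes, most of them matching the early light-induced ELIP1 or ELIP2, 0 were called, with a median of 1.055 (limma's camera adjusted p = 0.00275, upward). This call was lost with an estimated correlation (adjusted p = 0.995 by limma's camera). Some members of the family differed between the slides, and not in one direction. The ELIP1-like Mapoly0091s0080 and Mapoly0091s0079 read 6.68 and 6.58 on slide 1, and 0.69 and 0.49 on slide 2. The ELIP2-like Mapoly0047s0106 read 1.21 on slide 1 and 4.16 on slide 2. The median of the 79 genes was −0.63 (limma's camera adjusted p = 0.0102), with −1 on slide 1 and −0.36 on slide 2. The adjusted p was 0.873 with an estimated correlation and 0.211 without replicate 3, both by limma's camera. Of the 24 measured carbon fixation genes 0 passed, also when adjusted over the list alone, and their medians on replicates 1 to 4 were −1.89, −0.83, 0.00 and 0.34 (limma's camera adjusted p = 0.15). The chlorophyll synthesis list had 2 rises among 13 measured genes, both in chlorophyllases, Mapoly0008s0176 and Mapoly0008s0177 (2.01 ± 0.90), which break chlorophyll down.

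Cytochrome P450 genes moved both ways. Of 113 measured members 21 rose, 12 fell and 80 did not pass, and 26 rose and 19 fell when adjusted over the list alone. The CYP90A-like Mapoly0033s0061 rose by 4.26 ± 0.08 and the CYP76C4-like Mapoly0008s0192 by 2.63 ± 0.55. The kaurene oxidase-like Mapoly0140s0010, matching an enzyme of gibberellin synthesis, fell by 3.24 ± 0.29. Their median was 0.04 (limma's camera adjusted p = 0.0251), with −0.07 on slide 1 and 0.23 on slide 2. The adjusted p was 0.873 with an estimated correlation and 0.0576 without replicate 3, both by limma's camera. The 2-oxoglutarate dioxygenases had 3 rises, 3 falls and 29 not passing among 35 measured, with 4 and 3 when adjusted over the list alone. Mapoly0040s0122 rose by 5.14 ± 0.48 and Mapoly0019s0012 fell by 1.08 ± 0.42. The list median was 0.17 (limma's camera adjusted p = 0.0102, slide medians 0.30 and 0.16), it stood 0.315 above the median of all kept genes, and 0.359 above it after median centring, where the call was lost, and the adjusted p was 0.851 by limma's camera with an estimated correlation. Among NAC factors 2 of 7 rose, 0 fell and 5 did not pass, with 4 rises when adjusted over the list alone. The NAC028-like Mapoly0011s0176 rose by 1.27 ± 0.60. The list median was 0.84 (limma's camera adjusted p = 0.00996, slide medians 0.65 and 1.00), and the adjusted p was 0.851 by limma's camera with an estimated correlation.

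**Figure D3:**
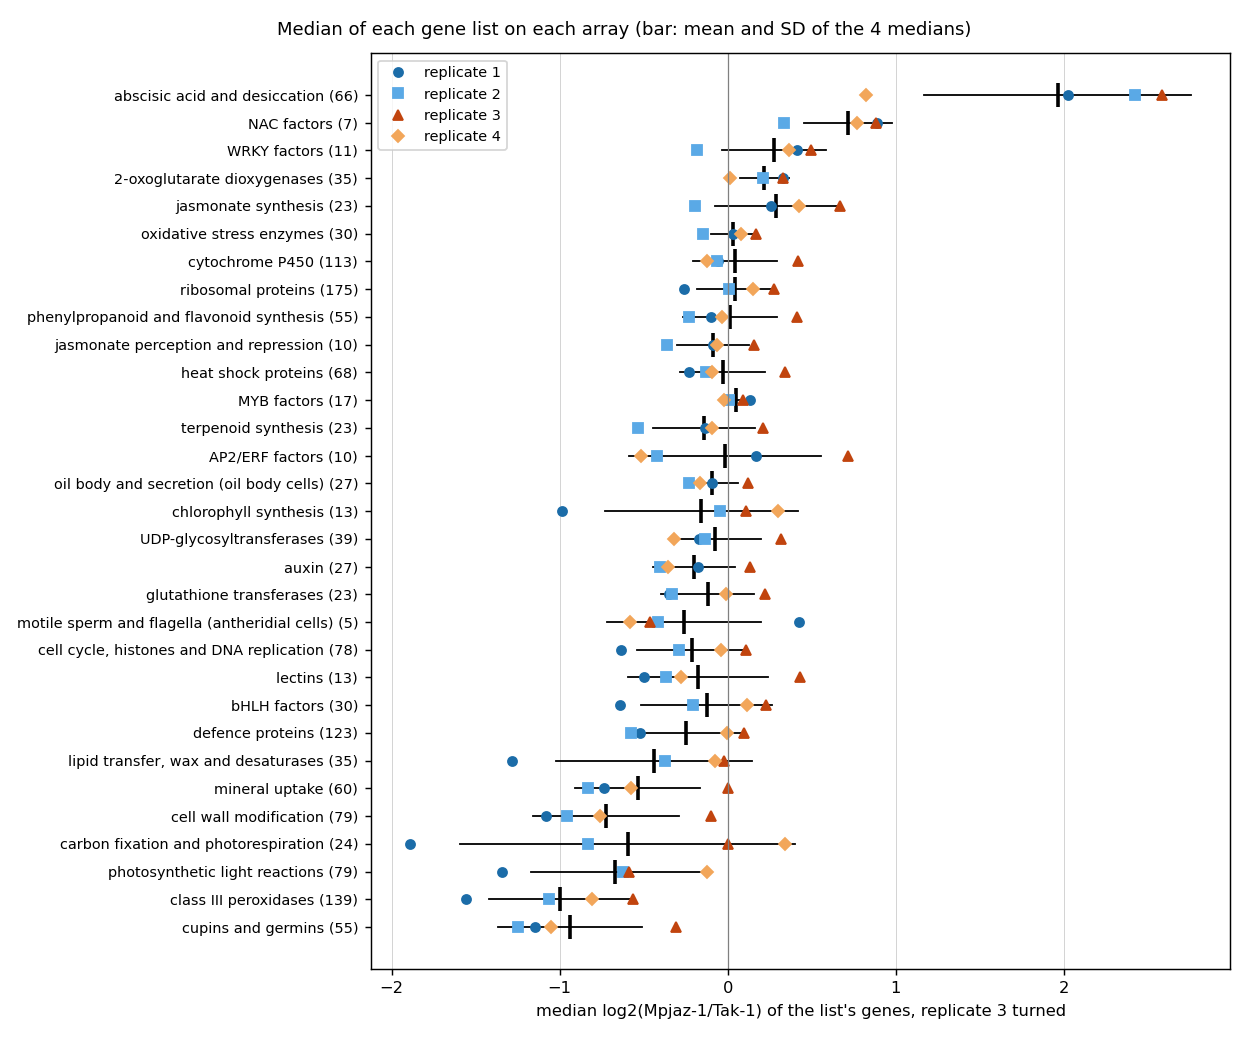
Median log2(Mpjaz-1/Tak-1) of the genes of each list on each array, with replicate 3 turned and the number of measured genes in brackets. Symbols are the 4 arrays, vertical ticks the mean of the 4 medians and horizontal bars 1 SD to each side. The abscisic acid and desiccation list has positive medians from 0.82 to 2.58, and the class III peroxidases and the cupins and germins have negative medians on each array.

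Of the 31 lists tested, 10 passed by limma's camera with its preset correlation, 5 upward and 5 downward, and 0 passed with an estimated correlation. The estimated correlations of the 10 ran from 0.055 to 0.356, above the preset 0.01. That setting had little power on 4 arrays, so its 0 does not show that the lists did not move. With the preset correlation 6 passed with the signs as labelled, and 8 passed without replicate 3. Called members then numbered 36 falls and 1 rise among class III peroxidases, and 10 falls among cupins and germins, 15 in cell wall modification and 7 in mineral uptake, each with 0 rises. They numbered 15 rises and 4 falls in abscisic acid and desiccation, 8 and 10 in cytochrome P450, 4 and 1 in jasmonate synthesis, 1 and 1 in 2-oxoglutarate dioxygenases, 0 in NAC factors and 1 fall in the photosynthetic light reactions. With the signs as labelled 0 members of any list were called. Camera compares the moderated t statistics of a list with those of the other genes, so its direction can differ from the sign of a median or mean log2 ratio. It did so in several lists that did not pass, among them defence proteins and bHLH, AP2/ERF and MYB factors. By fry, which asks whether a list's genes move one way on balance, the list of motile sperm and flagella passed (limma's fry adjusted p = 0.00875, median −0.21 over 5 genes), and no other list did. Its slide medians were 0.32 and −0.60, and its median without replicate 3 was 0.02.

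In terpenoid synthesis 4 of 23 measured genes rose and 2 fell, with 6 and 7 when adjusted over the list alone (limma's camera adjusted p = 0.548). The terpenoid cyclase genes Mapoly0108s0025 and Mapoly0108s0042 rose by 4.91 ± 0.94 and 4.59 ± 1.28, and a CPS1-like gene of gibberellin precursor synthesis (Mapoly0015s0008) fell by 1.86 ± 0.19. In phenylpropanoid and flavonoid synthesis 5 of 55 rose and 4 fell, with 6 and 4 when adjusted over the list alone (limma's camera adjusted p = 0.15). A chalcone synthase-like gene (Mapoly0070s0036) rose by 2.27 ± 0.64 and an HCT-like gene (Mapoly0003s0277) fell by 3.25 ± 1.04. Among bHLH factors 5 of 30 rose and 4 fell, with 7 and 7 when adjusted over the list alone (limma's camera adjusted p = 0.667). The TT8-like Mapoly0028s0058, matching a flavonoid regulator, rose by 4.49 ± 0.42. Among MYB factors 1 of 17 rose and 1 fell, with 1 and 2 when adjusted over the list alone (limma's camera adjusted p = 0.667). The MYB20-like Mapoly0090s0091 fell by 3.23 ± 0.58.

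Defence proteins went both ways, with 11 rises and 16 falls among 123 measured genes and 25 of each when adjusted over the list alone (limma's camera adjusted p = 0.964). A basic chitinase (Mapoly0116s0045) rose by 3.92 ± 0.91 and a CAP family gene (Mapoly0092s0055) by 3.33 ± 0.67. The thaumatin-like genes Mapoly0097s0013 and Mapoly0097s0002 fell by 3.05 ± 0.91 and 3.01 ± 0.82. Among auxin genes 1 of 27 rose and 4 fell, with the same counts when adjusted over the list alone (limma's camera adjusted p = 0.667). The PIN4-like efflux carrier Mapoly0089s0050 fell by 2.26 ± 0.50, and a GH3.2-like gene (Mapoly0053s0073), matching an enzyme that conjugates auxin to amino acids, rose by 2.84 ± 1.10. Lipid transfer, wax and desaturase genes had 6 falls and 0 rises among 35, with 10 and 1 when adjusted over the list alone (limma's camera adjusted p = 0.372). A glycolipid transfer gene (Mapoly0022s0179) fell by 1.51 ± 0.37.

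Ribosomal protein genes had 1 rise and 1 fall among 175 and 0 when adjusted over the list alone (limma's camera adjusted p = 0.0563). Cell cycle, histone and DNA replication genes had 3 falls among 78 and 0 when adjusted over the list alone, the 3 being kinesins such as the POK2-like Mapoly0029s0045 (−1.06 ± 0.23). Heat shock proteins had 3 rises and 3 falls among 68, with the same counts when adjusted over the list alone, the HSP17.6II-like Mapoly0045s0028 falling by 2.42 ± 0.67. Oxidative stress enzymes had 3 rises among 30, with 3 when adjusted over the list alone. The MDAR1-like Mapoly0001s0099, a monodehydroascorbate reductase, rose by 0.96 ± 0.33, a value that was −0.07 after median centring. Glutathione transferases had 2 falls among 23, lectins 1 fall among 13, and UDP-glycosyltransferases 1 rise and 3 falls among 39. Of the falls in UDP-glycosyltransferases, Mapoly0169s0030 was not well above background in Mpjaz-1 and was at least 1.89-fold lower there. WRKY factors had 1 rise among 11, the WRKY42-like Mapoly0039s0030 at 1.55 ± 0.72, and the AP2/ERF list 1 rise and 1 fall among 10. The rise was that of the ABI3-like B3 gene Mapoly0086s0035, which the text pattern caught by the words AP2/B3-like, and the fall was in the RAP2.11-like Mapoly0038s0075 (−0.96). The list of polyphenol oxidases and laccases had 1 measured gene, at −0.89, too few for a test.

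Of all genes kept, 10.1% were called. The motile sperm and flagella list, for antheridial cells, had 1 fall among 5 measured genes, the AIR9-like Mapoly0023s0068 (−1.91 ± 0.94). The text pattern caught this gene by the word dynein in its description, and whether it acts in sperm was not tested. Medians of the list on replicates 1 to 4 were 0.42, −0.41, −0.46 and −0.58. The oil body and secretion list had 4 falls and 0 rises among 27 (limma's camera adjusted p = 0.728). Of these, 3 were ABCG11-like genes that match an exporter of cuticular lipids, from −1.46 to −1.89, and the other was PDR6-like, Mapoly0021s0156 (−1.97 ± 0.94).

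Across genes, which are not independent replicates, Pearson's r was 0.87 between replicates 1 and 2 of slide 1. With replicate 3 turned it was 0.70 between replicates 3 and 4 of slide 2 and from 0.52 to 0.61 between arrays of different slides. Spearman's rho was lower, 0.82, 0.44 and from 0.31 to 0.45. A test of the difference between the slides called 0 genes by limma, with 2297 at an unadjusted p under 0.05 where chance gives 550 and a smallest adjusted p of 0.0817.

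**Figure D4:**
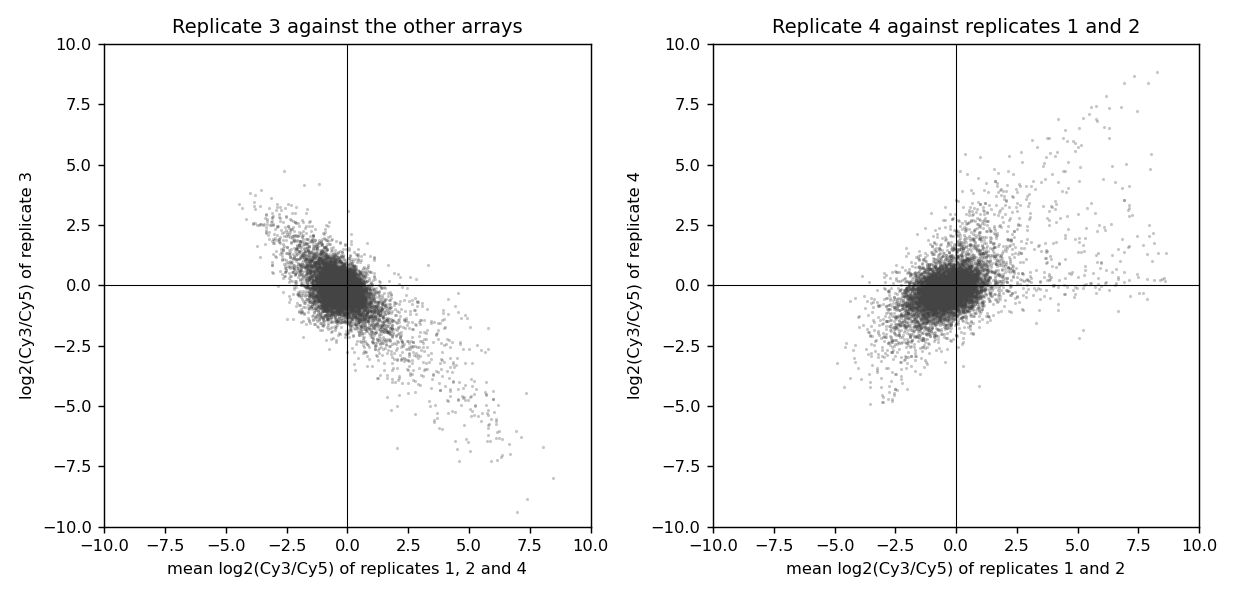
Log2(Cy3/Cy5) of each kept gene (points) on replicate 3 against the mean of replicates 1, 2 and 4 (left) and on replicate 4 against the mean of replicates 1 and 2 (right), with signs as labelled. Points on the left run from the upper left to the lower right, where r with the single arrays was from −0.61 to −0.70, and on the right upward, where r was 0.52 and 0.57.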

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

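The tests of exchanged dyes, of dye effects alone and of an opposite plant response were chosen only after the ratios of replicate 3 had been seen. Of 147 values examined for an array far from the other 3, 7 had one, and chance gives about 1 in 20. Replicate 4 of the LOX1-like Mapoly0420s0001 read −0.92 with replicate 3 turned, where the others lay from −1.95 to −1.81. Replicate 1 was the distant array in the MYB84-like Mapoly0034s0034 (0.48, others 2.21 to 2.36) and the ARF6-like Mapoly0075s0050 (−1.36, others −0.90 to −0.83). The same held for the lipid transfer gene Mapoly0120s0024 (−1.73, others −1.04 to −0.93) and the desaturase Mapoly0024s0114 (−2.09, others −1.17 to −1). The list median of cytochrome P450 genes was 0.42 on replicate 3 and from −0.13 to −0.06 on the others, and that of the motile sperm and flagella list was 0.42 on replicate 1 and from −0.58 to −0.41 on the others.

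Replicate 3 ran opposite to the other arrays. Of the genes called on replicates 1, 2 and 4 alone, 83.6% had the opposite Cy3/Cy5 sign on replicate 3, and 16.4% kept the sign, where gene-specific dye effects alone would keep it in most. Cy3 background or normalization is argued against by the brightest 25% of genes, in which r with the mean of the other arrays was −0.881. Exchanged dyes on replicate 3 relative to the labels stay open, and the 83.6% does not support them, since it restates the pattern that led to the test. An opposite response of the plants of replicate 3 cannot be told apart from exchanged dyes by the ratios (slope of the turned array on the others 0.808), since both turn every ratio. The authors' deposited table carries replicate 3 alone with the sign opposite to its Cy3/Cy5 ratio (r = −0.99), which does not say why.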

How the results depend on the processing

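Turning replicate 3 and the dye term were added after the data were seen. Choices other than the sign of replicate 3 left the count at 0 with the signs as labelled, except slide 1 alone (3291 genes) and leaving out single arrays (0 to 646). Turning replicate 3 gave 1108 genes, or 233 with a dye term, and raised the lowest correlation between arrays to 0.52. With it turned, higher and lower genes numbered 109 and 92 after median centring, 826 and 1024 with each probe tested by itself, and 935 and 1467 with slide as a block. They were 893 and 2398 on slide 1, 156 lower on slide 2, 44 and 60 with a trended and robust variance, 702 and 1115 with separate channels, 123 and 110 with a dye term and 0 and 0 as labelled. Without single arrays they ran from 186 to 289 and from 126 to 460.

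As labelled, the log2 ratio of MpJAZ was 1.44 on slide 1, −0.0182 after median centring, 1.68 with replicate 3 turned, 1.76 with a dye term too, and 0.33 to 1.61 without single arrays. Turned, it lost its call after median centring (1.22), with a trended and robust variance (1.68) and as labelled (0.73). Over its other alternatives it kept its call, from 0.91 with no background correction to 2.08 with Agilent's processed signals, and from 1.59 to 1.82 without single arrays. Gene lists passing as labelled numbered 3 after median centring, 0 with no filter, 2 on slide 2, 10 turned, 11 with a dye term and 4 to 8 without single arrays. Turned, 6 passed after median centring, 6 as labelled and 8 to 12 without single arrays.

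The list of jasmonate synthesis lost its call with no filter (median 0.022), on slide 1 (0.031) and as labelled (−0.12), and its median ran from 0.04 to 0.25 without single arrays. Cytochrome P450 lost it with no background correction (0.065), no filter (0.089), on slide 1 (−0.066) and as labelled (−0.16), and its median ran from −0.04 to 0.11 without single arrays. The 2-oxoglutarate dioxygenases lost it after median centring (−0.16), with no filter (0.086), with the strict filter (0.42) and on slide 2 (0.16), and ran from 0.11 to 0.25 without single arrays. NAC factors lost it after median centring (0.18), on slide 1 (0.65) and as labelled (0.16). Photosynthetic light reactions lost it after median centring (−1.53) and on slide 1 (−1). As labelled the direction of the test turned, not the sign of the median (−0.39), which ran from −0.87 to −0.42 without single arrays. Mineral uptake lost it with no background correction (−0.17), median centring (−0.76), no filter (−0.11), the strict filter (−0.46) and on slide 2 (−0.24). The size of change depended on the background correction. From no correction to Agilent's processed signals, the median of abscisic acid and desiccation went from 1.28 to 3.55. That of class III peroxidases went from −0.29 to −1.49. Cupins and germins went from −0.31 to −1.32, and cell wall modification from −0.125 to −0.915. Mapoly0001s0099 turned to −0.0679 after median centring. Fewer arrays leave fewer degrees of freedom and the strict filter leaves 6168 genes, and the cause of the other changes was not tested. Of 113 other named genes, 111 kept their call with the authors' deposited table, 41 after median centring, 30 with a trended and robust variance and 37 with a dye term. Without replicates 1 to 4 in turn 59, 53, 63 and 60 kept it, and on slides 1 and 2 alone 101 and 58. With slide as a block all 113 kept it. That term leaves each mean unchanged and takes the slide difference out of the error. Keeping a call under it therefore does not show that arrays of a slide are independent, as the main fit takes them to be. Cy3 signal over background limits the dim genes. The fit of 1 ratio per array is itself paired within arrays.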

Other observations

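The tests of families were planned before their results were seen, and the families and genes named here were chosen by those results. With replicate 3 turned, families outside the fixed lists held called genes, mostly lower in Mpjaz-1. Of 9 measured tonoplast aquaporin genes (delta tonoplast integral protein), which carry water across the vacuole membrane, 6 fell and 0 rose, with a median of −2.45. Of 11 genes matching the proton pump AHA11, 6 fell and 1 rose, with a median of −1.47. The elongation factor Tu family had 7 falls among 14 genes, fasciclin-like arabinogalactan proteins of the cell wall 4 among 8, cupredoxins 6 falls and 1 rise among 20, and leucine-rich repeat kinases 9 falls and 1 rise among 61. The DUF567 family, of unknown function, had 11 falls and 3 rises among 24 genes. Heavy metal transport genes went the other way, with 6 rises and 0 falls among 17. Of the 93 families of at least 8 genes outside the lists, 9 passed by limma's camera with the preset correlation, the ninth being one matching the trithorax-related gene ATXR6, with 0 genes called among 21. With an estimated correlation all 9 calls were lost (adjusted p = 0.995 by limma's camera), a setting with little power on so few arrays.

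Ratios of carbon fixation genes differed between the slides, with medians of −1.39 on slide 1 and 0.15 on slide 2, a difference of −1.54. The difference passed by limma's camera with the preset correlation (adjusted p = 0.000161) and not with an estimated one (adjusted p = 0.931). The estimated setting had little power on so few arrays. The lists of abscisic acid and desiccation (2.22 and 1.73) and of lipid transfer, wax and desaturases (−0.77 and −0.04) also passed with the preset correlation (adjusted p = 0.0414 by limma's camera), and 0 lists passed with an estimated one. In abscisic acid and desiccation, replicate 3 of slide 2 had the highest median (2.585) and replicate 4 the lowest (0.824). For carbon fixation genes, wider ratios on slide 1 are argued against, since the difference was −1.37 after the arrays were scaled to one spread. Dim signals in Cy3 are argued against as well, since the 19 members well above background in both channels differed by −1.61. A difference between the plants of the slides and the slides themselves cannot be told apart (−1.54), because each slide held its own plants.

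Genes called in one direction lay beside each other more often than chance gives. Of neighbouring pairs by gene number 127 were called the same way where 1000 permutations gave 32.3 on average and at most 50. With copies left out, taken as pairs that share a best match, an annotation text or probe sequence, 74 remained where 31.0 were expected, a ratio of 2.38, so close copies that share probes are argued against as the whole cause. In a test added after that result, among pairs with annotation on both genes the count was 28 against 21.5, within the highest permutation of 37, so copies without annotation stay open. A genomic region that differs between the lines stays open. The scaffold with the most called genes held 27.8%, where over 40% had been set as the bound, but a region smaller than a scaffold need not reach that bound. On that scaffold each gene from Mapoly0117s0053 to Mapoly0117s0057 rose, and these genes have no annotation.

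Other sign patterns of the 4 arrays, 8 in all, are too few for a share under 0.05. Turning replicate 3 gave 1108 genes as 1 of them, and the highest of the other patterns gave 0. For the signs as labelled, with 0 genes, all 8 patterns gave as many, up to 1108. When the 8 channels were quantile normalized and taken as unpaired samples, unlike the alternative with separate channels, which keeps both channels of a spot correlated (1817 genes), the split by genotype with replicate 3 turned gave 1718 genes, and 1 of the 35 splits into 4 and 4 gave as many, the highest of the others being 0. The sign of replicate 3 had been turned after its ratios were seen, so the split was chosen from the data and its share does not bear on chance, nor on which group was the mutant.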
